A study of Mus musculus with 32 samples.

How the data were processed

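Global gene expression was measured in 32 cDNA samples from mouse cells, each on one 1-colour Affymetrix mouse expression array. Per the labels' protocols, total RNA was extracted, cDNA of about 20000 cells was amplified by global PCR and biotin-labelled cRNA was hybridised. EpiLCs were harvested after 36 h and aggregated at 2000 cells per well. Transgenes were switched on with doxycycline at 1.5 μg/ml, and cytokine induction used BMP4 and BMP8A at 500 ng/ml each, SCF at 100 ng/ml, EGF at 50 ng/ml and LIF at 1000 U/ml. The newly submitted cells are labelled as male with a mixed background that includes C57BL/6, and the earlier arrays as C57BL/6, with the epiblast and PGCs of unknown sex. BP14A ESCs with doxycycline were sorted for the stella-ECFP reporter; the labels name no sort for the PGCLCs. The design text calls the arrays biological duplicates, and no label names separate cultures, so p-values measure the spread between these arrays, part of which may be technical.

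The authors' deposited values are 1 value per probe set and array on a log2 scale, from 0 to 14.59. The summarisation, background correction and normalization software are not given in the sources used here. The log2 scale was read from the values, which have 2 decimals and the range that a 16-bit scanner gives. Since they are already log2 values, no pseudocount was needed and the alternatives set for it did not apply. The deposited array medians ran from 4.62 to 4.78. Their range of 0.16 exceeded the tolerance of 0.1 set for values to be used as they stand, so the arrays were quantile normalized, which gives each array the same distribution and hides any change in total RNA per cell. The deposited values and median centring were alternatives.

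The table held 45101 probe sets. The 64 control probe sets were left out. GEO's platform annotation listed 35890 probe sets, 34945 of them with 1 gene symbol and 932 with several; 9160 more, controls aside, were not listed. Only probe sets with 1 symbol named a gene, and 34741 of these had a gene identifier that matched the RefSeq gene table of assembly GRCm38.p6, which was used for current symbols and to tell which genes lie on the Y chromosome. No coordinates are given because no build is tied to the array annotation. Of 18193 genes, 9183 had 1 probe set. The others took the probe set with the highest mean over all arrays, which the mean of all probe sets replaced as an alternative. A gene was tested if at least 1 group mean reached the 40th percentile of all values (log2 4.05), which left 15497 genes.

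All 32 arrays entered one limma model (version 3.58.1 in R 4.3.3; data.table version 1.17.8) with a mean for each of the 16 groups and 16 residual degrees of freedom, so that groups of 2 arrays share an estimate of spread. Each comparison was a contrast within the new or within the earlier arrays, and 3 contrasts tested interactions. A gene was counted as higher or lower at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold, and only such genes are said to have risen or fallen. No array was a copy of its replicate (0 pairs had every value equal). Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 23 lists within a comparison, with an estimated correlation as an alternative; of 208 calls, 133 hold with it. The adjusted p beside each list with its call lost is given in the text. Medians of lists were also set against 10000 random lists matched on mean expression. Where a single count of list members is given, the count adjusted over the list alone was equal. The median and mean of a list differed in sign in 75 of 598 tests, and in 0 of these had camera made a call against the sign of the median.

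The lists held 329 genes, of which 311 were measured and 301 tested. The others, among them Nanos3, T, Hoxb8, Tdg, Suv39h1, Tcf7, Ccnb1, Bax, Eno1, Fbn1 and Ddx3y, were not analysed here. The comparisons, tests, lists, other settings and the rule for named genes were fixed before the data were examined. The rule took, in each comparison, the 6 largest rises and 6 largest falls among counted genes whose arrays did not overlap, leaving out symbols that are clone or model numbers. From each list it took, among counted members, up to 2 with the largest rise and 2 with the largest fall. It also took a fixed set that included Prdm1, Prdm14, Tfap2c (each probe set), Dppa3, Nanos3, Dnd1, Kit, T, Hoxb1, Nanog, Sox2, Pou5f1, Klf4, Otx2, Fgf5, Dnmt3b, Uhrf1, Ehmt1 and Ehmt2. From these genes the text names those that describe each comparison and, a choice made after their values were seen, mostly those whose call held without each array in turn.

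The alternatives set beforehand were other normalizations, filters (none, or the 60th percentile), an empirical Bayes fit with trend and robust options, a block for replicate number, an adjusted p under 0.01, no fold limit, fits on fewer arrays and leaving out each array in turn. After the data were seen, RNA quality was added as an alternative, both as a covariate (the Gapdh 5′ minus 3′ difference of each array) and by leaving out 5 arrays under -2.5 while keeping 1 array per group. Agreement between routes was measured by Pearson's correlation across genes beside 100 simulations of unchanged groups against the same controls.

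The gene test was tested on simulated data for Ck-PGCLC day 2 against EpiLC, with 15497 genes and 40 genes changed per fold size. It counted 5% of genes changed 1.5-fold, 17.5% at 2-fold, 52.5% at 3-fold, 95% at 4-fold and 97.5% at 8-fold, and 4 of its 114 counted genes (3.51%) were unchanged ones. A shifted list was called, and 0 of 22 other lists were. The simulated noise was drawn independently for each gene, so it held no inter-gene correlation. It therefore cannot show how many list calls such correlation brings about. In that simulation changes near 2-fold were thus mostly missed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.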

Results

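Gene expression was measured on Affymetrix mouse expression arrays in cells on the way from pluripotency to the germ line. Primordial germ cells (PGCs) are the embryonic founders of sperm and eggs. PGC-like cells (PGCLCs) are their counterparts made in culture from epiblast-like cells (EpiLCs), which are themselves derived from embryonic stem cells (ESCs). PGCLCs were induced either by cytokines led by BMP4 (Ck-PGCLCs) or by doxycycline-driven transgenes, without cytokines. The transgenes coded for the transcription factors Blimp1 (gene Prdm1, written B), Prdm14 (P14) and Tfap2c (A), and cells are named by their factors as BP14A, BP14, P14A and P14 cells. The 32 arrays fell into 16 groups of 2 biological duplicates. The 22 newly submitted arrays covered BP14A cells at days 2 and 4, BP14, P14A and P14 cells at day 2, Ck-PGCLCs at days 2 and 4, EpiLCs after 36 h, BP14A ESCs without and with doxycycline, and parental cells. The parental clone carried no factor transgenes, received doxycycline at day 2 and served as the negative control (parental +Dox cells). The EpiLCs and Ck-PGCLCs were of the parental clone too, so factor-induced cells differ from them in clone as well as in treatment, and so do the BP14A ESCs. The 10 arrays from an earlier series covered ESCs, EpiLCs after 48 h, Ck-PGCLCs at day 6, the epiblast at embryonic day 5.5 and PGCs at embryonic day 9.5.

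Array medians lay between 4.62 and 4.78 on the log2 scale before normalization, and replicate arrays correlated at r = 0.9663 to 0.986 across the 15497 tested genes. Pairs of arrays from different groups correlated at 0.8792 to 0.9881, so the closest of these pairs lay above every replicate pair. Levels are given below as mean log2 expression ± SD (n = 2 arrays), and changes as log2 differences with the standard error (SE) and Benjamini-Hochberg adjusted p of limma. The number of arrays limits the precision, and levels under 4.05 were treated as dim, so a fold against a dim group is imprecise, and its rank among other folds too. The Gapdh 5′ minus 3′ probe set difference, a measure of RNA quality in which low values mark 3′-biased cDNA, was -4.66 and -2.99 in BP14A day 4 cells. It was -4.07 in 1 BP14 array, -3.03 in 1 EpiLC array, -2.82 in 1 array of untreated BP14A ESCs and -3.13 in 1 array of BP14A ESCs with doxycycline. The others lay above -2.5.

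The factor genes themselves were read first. Prdm1 stood at 4.21 ± 0.61 in EpiLCs and 5.63 ± 0.20 in parental +Dox cells, against 10.19 ± 0.08 in BP14A, 10.03 ± 0.24 in BP14, 10.07 ± 0.03 in P14A and 10.23 ± 0.09 in P14 cells at day 2. It was thus as high in cells labelled without a Blimp1 transgene as in cells labelled with one. Prdm14 stood at 2.86 ± 0.02 in parental +Dox cells and between 8.47 ± 0.21 in BP14A and 9.51 ± 0.45 in BP14 cells. The brightest Tfap2c probe set stood at 7.14 ± 0.14 in parental +Dox cells and 11.66 ± 0.08 in P14 cells, which carried no Tfap2c transgene. The 2 other Tfap2c probe sets gave 9.98 ± 0.12 and 10.14 ± 0.01 in P14 cells, against 5.96 ± 0.09 and 5.33 ± 0.08 in parental +Dox cells. In BP14A ESCs with doxycycline, Prdm1 stood at 7.91 ± 0.00, and its difference from ESCs without doxycycline did not pass the test (log2 change -0.09, adjusted p = 0.919). Nor did that of Tfap2c (log2 change -0.05, adjusted p = 0.949). Whether the probe sets read the transgenes depends on which part of each transcript the transgenes carry, which was not examined here, so these levels check no label.

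The EpiLCs, the starting cells of each induction, had left the naive pluripotent state. Of the naive pluripotency genes, 12 of 14 tested genes fell (camera adjusted p = 5.75e-18). Klf4 fell (log2 change -7.33, SE 0.71, adjusted p = 1.8e-07), with Tfcp2l1, another naive state transcription factor, at -7.19 (SE 0.28). Primed epiblast genes rose, among them the growth factor gene Fgf5 (log2 change 7.35, SE 0.41, adjusted p = 1.12e-10), Pou3f1 at 6.96 (SE 0.39) and the de novo DNA methyltransferase gene Dnmt3a at 6.03 (SE 0.27). On that list, 8 of 15 tested genes rose and 1 fell (camera adjusted p = 3.47e-06). Of the early germ cell genes, 9 of 13 tested genes fell (camera adjusted p = 7e-09), led by Prdm14 (log2 change -7.06, SE 0.25, adjusted p = 5.79e-13) and Tfap2c at -5.31 (SE 0.29). WNT response genes also fell, with 6 of 13 tested genes lower (camera adjusted p = 7.65e-05), and the WNT target Sp5 changed by -6.21 (SE 0.48). Cholesterol synthesis genes rose in 5 of 10 cases (camera adjusted p = 0.00128). Of the later germ cell and meiosis genes, 8 of 16 tested genes rose (camera adjusted p = 0.000224 and adjusted p = 0.094 with an estimated correlation), led by the piRNA pathway gene Mael (3.65). In all, 1111 genes were higher and 1154 lower in EpiLCs than in BP14A ESCs among 15497 tested. The Y-linked gene Eif2s3y was also higher in EpiLCs (log2 change 4.28, SE 0.28, adjusted p = 9.4e-10), being low in the BP14A ESCs at 5.15 ± 0.46. In the earlier series, EpiLCs against ESCs gave 1125 higher and 1099 lower genes. There 12 of 14 naive genes were lower (camera adjusted p = 5.22e-16) and 11 of 15 primed epiblast genes were higher with 1 lower (camera adjusted p = 3.27e-08). Fgf5 rose (log2 change 7.32, SE 0.41, adjusted p = 2.03e-10), and of the FGF and ERK response genes, 7 of 13 tested genes rose (camera adjusted p = 1.06e-05), led by Egr1 at 6.24 (SE 0.29).

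**Figure D1:**
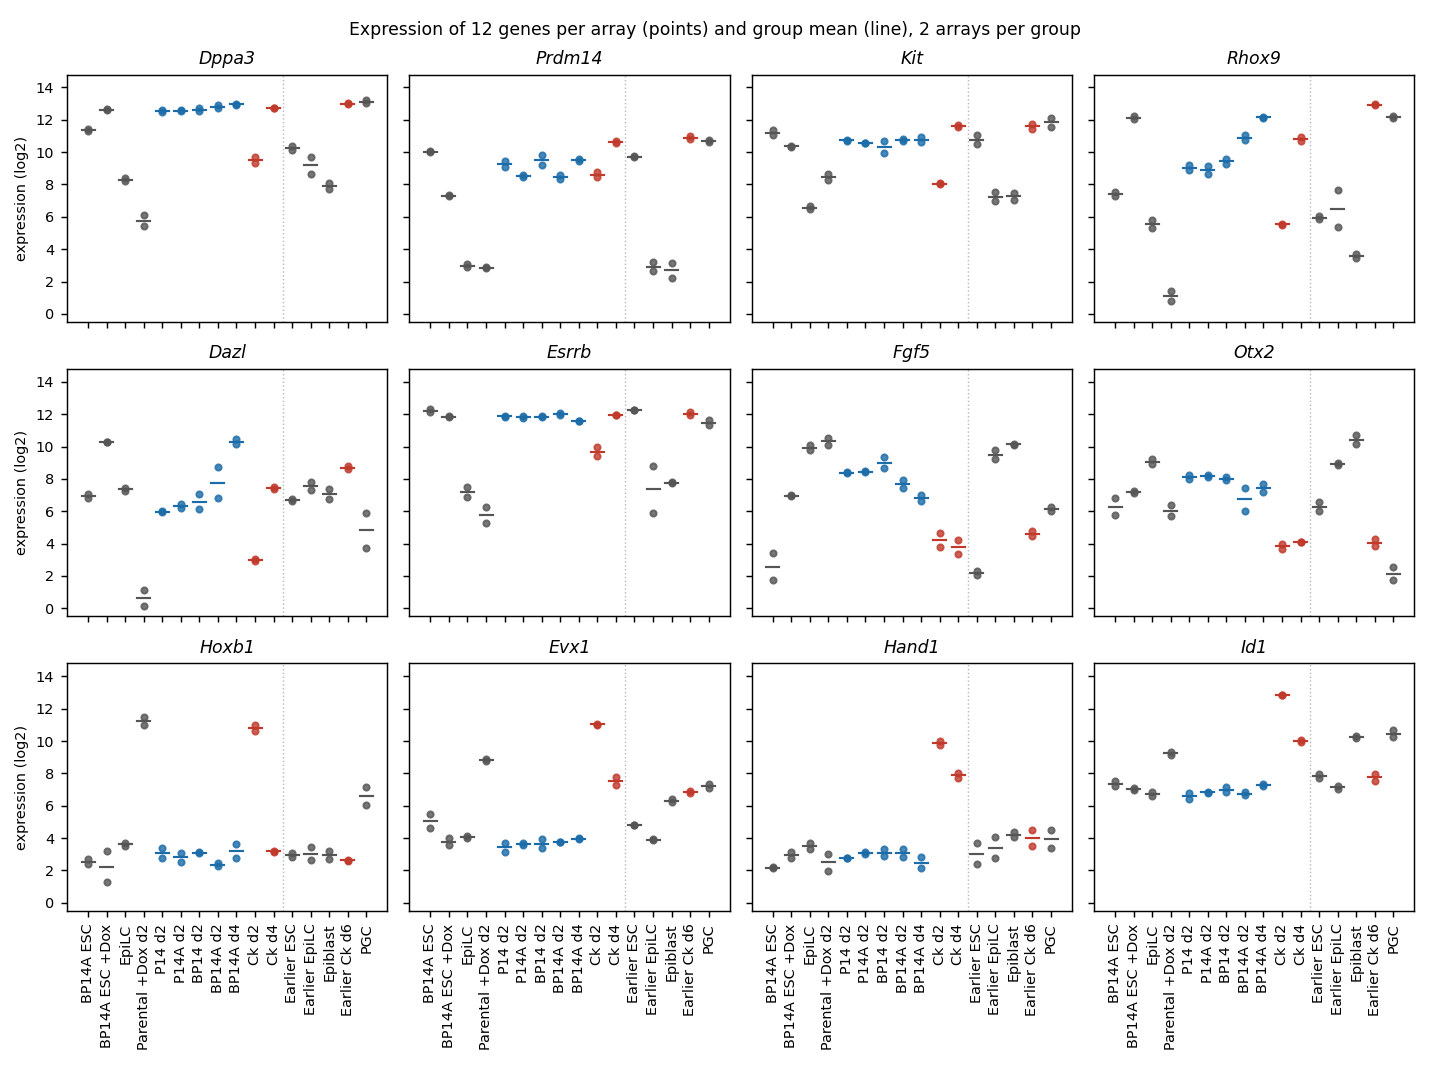
Log2 expression of 12 genes (y axis) in each array (points) of the 16 groups (x axis), with the group mean as a line; transcription factor-induced cells are blue, cytokine-induced cells red and all others grey, and the dotted line parts the 22 new arrays from the 10 earlier ones. Hoxb1 and Evx1 were high in cytokine-induced cells and parental +Dox cells at day 2 but not in BP14A, BP14, P14A or P14 cells, while Dppa3, Kit and Rhox9 were high in the factor-induced cells.

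Ck-PGCLCs at day 2 differed from EpiLCs along 2 lines. Posterior and primitive streak genes rose steeply, among them Cdx2, a homeobox gene of the posterior embryo and trophoblast, which went from 1.07 ± 0.53 to 9.07 ± 0.08 (SE of the change 0.79, adjusted p = 2.72e-07). The WNT agonist gene Rspo3 rose by 7.88 (SE 0.45), Lhx1 by 7.07 (SE 0.68) and Evx1 by 6.95 (SE 0.24). Of the primitive streak and mesoderm genes, 19 of 24 tested genes rose (camera adjusted p = 1.81e-19, with 21 higher when adjusted over the list alone). Germ cell regulators rose in the same cells, with Prdm14 at 5.63 (SE 0.25), Tfap2c at 4.85 (SE 0.29) and Prdm1 at 4.30 (SE 0.33). Of the early germ cell genes, 9 of 13 tested genes rose and 1 fell (camera adjusted p = 3.87e-06), the fall being in the X-linked homeobox gene Rhox5 (-3.76).

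Targets of BMP signalling were raised as well. In the BMP response list, 8 of 12 tested genes rose (camera adjusted p = 5.57e-08, with 9 higher when adjusted over the list alone), led by Id1 (log2 change 6.12, SE 0.19, adjusted p = 1.03e-13), a direct BMP target. Of the WNT response genes, 7 of 13 tested genes rose (camera adjusted p = 4.97e-07), with Sp5 at 5.70 (SE 0.48). The Hox gene Hoxb1 rose from 3.62 ± 0.12 to 10.82 ± 0.27. Of the naive pluripotency genes, 10 of 14 tested genes rose and 3 fell (camera adjusted p = 0.000229). Tfcp2l1 changed by 4.06 (SE 0.28) and Nanog by 3.31 (SE 0.45). Of the trophoblast genes, 6 of 14 tested genes rose and 2 fell (camera adjusted p = 0.00504 and adjusted p = 0.108 with an estimated correlation); among those that rose were Cdx2 and Gata3 (6.35), which mesoderm also uses.

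Primed epiblast and de novo methylation genes fell in Ck-PGCLCs at day 2. Pou3f1 changed by -5.75 (SE 0.39), Fgf5 by -5.70 (SE 0.41) and Dnmt3l, the cofactor of the de novo methyltransferases, by -6.48 (SE 0.26). Of the primed epiblast genes, 2 of 15 tested genes rose and 8 fell (camera adjusted p = 4.63e-05), and of the DNA methylation genes, 1 of 12 tested genes rose and 6 fell (camera adjusted p = 0.0014). Later germ cell and meiosis genes went down rather than up, as 12 of 16 tested genes fell (camera adjusted p = 3.29e-12), with Mael at -5.92 (SE 0.34). The lists of core pluripotency (camera adjusted p = 0.0371 and adjusted p = 0.233 with an estimated correlation), glycolysis and hypoxia (camera adjusted p = 0.0137 and adjusted p = 0.108 with an estimated correlation) and unfolded protein response (camera adjusted p = 0.0324 and adjusted p = 0.108 with an estimated correlation) were shifted down, and that of p53 response up (camera adjusted p = 0.0314 and adjusted p = 0.108 with an estimated correlation). Cholesterol synthesis genes fell as well, in 8 of 10 cases (camera adjusted p = 6.3e-07). In all, 1305 genes were higher and 939 lower than in EpiLCs. With the deposited values, without quantile normalization, the split was 1621 higher and 713 lower.

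By day 4 fewer streak genes and more early germ cell genes were raised in the cytokine-induced cells. Against EpiLCs, Prdm14 stood at 7.64 (SE 0.25), Tfap2c at 6.98 (SE 0.29) and Prdm1 at 6.38 (SE 0.33), and the germ cell genes Dppa3 and Kit at 4.40 (SE 0.25) and 5.06 (SE 0.26). Of the early germ cell genes, 12 of 13 tested genes rose and 1 fell (camera adjusted p = 1.16e-15). Naive pluripotency genes rose (11 higher and 1 lower of 14, camera adjusted p = 4.03e-09), and so did the core pluripotency gene Sox2 (2.30 (SE 0.20)). Among primed epiblast genes, 1 of 15 tested genes rose and 11 fell (camera adjusted p = 4.03e-09), and Dnmt3b changed by -5.20 (SE 0.61). The carbonyl reductase gene Cbr3 fell (log2 change -7.72, SE 0.34, adjusted p = 5.38e-12), and the lactate transporter gene Slc16a3 changed by -6.20 (SE 0.49). Of the primitive streak and mesoderm genes, 10 of 24 tested genes rose and 1 fell (camera adjusted p = 0.000128). In the BMP response list, 7 of 12 tested genes rose (camera adjusted p = 3.81e-05), and in the WNT response list, 7 of 13 tested genes rose and 1 fell (camera adjusted p = 0.00348 and adjusted p = 0.0743 with an estimated correlation). In total, 1394 genes were higher and 1147 lower.

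Within the cytokine route, the step from day 2 to day 4 lowered 19 of 24 streak genes (camera adjusted p = 1.81e-13). Mixl1, a mesendoderm homeobox gene, fell from 8.83 ± 0.17 to 2.18 ± 2.26 (log2 change -6.65, SE 0.74, adjusted p = 1.65e-06), and Hoxb1 changed by -7.63 (SE 0.46). The activin antagonist gene Fst fell to a dim level (log2 change -8.09, SE 0.41, adjusted p = 2.01e-10). Early germ cell genes rose in 11 of 13 cases (camera adjusted p = 1.81e-13), led by Rhox9 at 5.28 (SE 0.43) and the integrin gene Itgb3 at 4.65 (SE 0.46), and Dppa3 rose by 3.20 (SE 0.25). Later germ cell genes rose too, as 9 of 16 tested genes rose (camera adjusted p = 6.38e-06), with the RNA-binding protein gene Dazl at 4.45 (SE 0.56). Of the p53 response genes, 3 of 10 tested genes fell (camera adjusted p = 1.52e-05), and of the core pluripotency genes, 5 of 11 tested genes rose (camera adjusted p = 4.89e-06, with 6 higher when adjusted over the list alone). The histone methyltransferase gene Ehmt1 fell (log2 change -1.15, SE 0.24, adjusted p = 0.00126), from 10.13 ± 0.16 to 8.98 ± 0.14. This step changed 881 genes upward and 1060 downward.

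BP14A cells at day 2, induced without cytokines, had higher early germ cell genes than EpiLCs and few raised streak genes. Rhox9 stood at 5.34 (SE 0.43); Tfap2c at 6.50 (SE 0.29), Prdm1 at 5.97 (SE 0.33) and Prdm14 at 5.48 (SE 0.25) are the genes of the transgenes. Dppa3, a maternal and germ cell factor also called stella, rose from 8.31 ± 0.14 to 12.80 ± 0.15, and Kit, the receptor that PGCs need for migration and survival, rose by 4.17 (SE 0.26). Of the early germ cell genes, 12 of 13 tested genes rose and 1 fell (camera adjusted p = 5.54e-18), and without the 3 factor genes 9 of 10 rose and 1 fell (camera adjusted p = 3.12e-11). Of the later germ cell genes, 4 of 16 tested genes fell (camera adjusted p = 0.15, with 5 lower when adjusted over the list alone), with Mael at -2.55 (SE 0.34). The naive gene Klf2 rose by 5.39 (SE 0.30), and of its list 8 of 14 tested genes rose and 2 fell (camera adjusted p = 0.000109). Of the primitive streak and mesoderm genes, 2 of 24 rose and 1 fell (camera adjusted p = 0.926), with Fgf17 at 1.71 (SE 0.33). The BMP response list was not shifted (camera adjusted p = 0.926), nor was the WNT response list (camera adjusted p = 0.926).

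Primed epiblast genes fell in BP14A cells at day 2, as 1 of 15 tested genes rose and 11 fell (camera adjusted p = 4.44e-10, with 1 higher and 12 lower when adjusted over the list alone). Pou3f1 changed by -5.48 (SE 0.39), Dnmt3b by -3.88 (SE 0.61), Fgf5 by -2.23 (SE 0.41) and Otx2 by -2.34 (SE 0.39). Of the cholesterol synthesis genes, 6 of 10 tested genes fell (camera adjusted p = 5.08e-07). In the glycolysis and hypoxia list, 1 of 15 tested genes rose and 5 fell (camera adjusted p = 0.00768 and adjusted p = 0.125 with an estimated correlation), with the lactate dehydrogenase gene Ldha at -3.26 (SE 0.33), and in the p53 response list, 1 of 10 tested genes rose and 3 fell (camera adjusted p = 0.0283 and adjusted p = 0.135 with an estimated correlation), with Cdkn1a at -2.58 (SE 0.51). The p53 response call ended with the deposited values (adjusted p = 0.0575). In all, 969 genes were higher and 830 lower. Fitted on the 4 arrays of these groups alone, with fewer degrees of freedom, the total of 1799 became 1123.

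BP14A cells at day 4 kept high germ cell genes. Rhox9 stood at 6.60 (SE 0.43) over EpiLCs, Rhox6 at 5.82 (SE 0.39), Prdm14 at 6.54 (SE 0.25) and Dppa3 at 4.65 (SE 0.25). Of the early germ cell genes, 12 of 13 tested genes rose (camera adjusted p = 3.15e-18), of the naive genes, 8 of 14 tested genes rose and 2 fell (camera adjusted p = 3.46e-06, with 11 higher and 2 lower when adjusted over the list alone), and of the primed epiblast genes, 1 of 15 tested genes rose and 11 fell (camera adjusted p = 1.56e-07). Dazl rose by 2.94 (SE 0.56) and Stk31 by 2.08 (SE 0.34), and the later germ cell list held 4 higher and 3 lower of 16 (camera adjusted p = 0.561). Of the cholesterol synthesis genes, 6 of 10 tested genes fell (camera adjusted p = 1.65e-06, with 7 lower when adjusted over the list alone). The totals were 1258 higher and 914 lower genes, and 1573 and 715 with median centring in place of quantile normalization. Both BP14A day 4 arrays had low Gapdh 5′ minus 3′ differences (-4.66 and -2.99), against -3.03 in the lower EpiLC array.

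Between days 2 and 4, BP14A cells changed far less than cytokine-induced cells did. The neural gene Sox1 rose from 0.59 ± 0.83 to 6.22 ± 0.44 (log2 change 5.63, SE 0.56, adjusted p = 4.92e-05), Dnmt3l rose by 2.80 (SE 0.26), the keratin genes Krt8 and Krt18 by 2.21 (SE 0.25) and 1.73 (SE 0.24), and Pax6 by 2.31 (SE 0.36). The zinc finger gene Bcl11a fell (log2 change -2.42, SE 0.29, adjusted p = 0.000179), as did Etv4 (-2.13 (SE 0.32)). With the mean of all probe sets the calls of Sox1 (2.60), Pax6 (0.46) and Bcl11a (-0.59) ended. Of the later germ cell genes, 2 of 16 tested genes rose (camera adjusted p = 1.7e-05 and adjusted p = 0.13 with an estimated correlation, with 5 higher when adjusted over the list alone), of the trophoblast genes, 3 of 14 tested genes rose (camera adjusted p = 4.51e-07, with 6 higher when adjusted over the list alone), of the neural and surface ectoderm genes, 2 of 13 tested genes rose (camera adjusted p = 0.0277 and adjusted p = 0.288 with an estimated correlation, with 3 higher when adjusted over the list alone), and of the glycolysis and hypoxia genes, 2 of 15 tested genes rose (camera adjusted p = 1.7e-05, with 5 higher when adjusted over the list alone). The totals were 145 higher and 77 lower, or 195 and 57 with the deposited values. The total of 222 became 60 without BP14A day 4 replicate 1, 132 without its replicate 2, 137 without BP14A day 2 replicate 1, 73 without its replicate 2 and 134 with the Gapdh difference as a covariate. Limma counted 0 genes when only these 4 arrays were fitted, with 1966 at unadjusted p under 0.05 there and 2255 over all arrays.

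Set directly against cytokine-induced cells at day 2, BP14A cells had lower posterior mesoderm genes and higher germ cell genes. Hoxb1 was lower (log2 change -8.46, SE 0.46, adjusted p = 1.55e-10), at the dim level of 2.36 ± 0.13 against 10.82 ± 0.27. The receptor gene Pdgfrb stood at -7.81 (SE 0.72), Cdx2 at -7.57 (SE 0.79), Evx1 at -7.27 (SE 0.24) and Fst at -7.69 (SE 0.41). Of the primitive streak and mesoderm genes, 19 of 24 tested genes were lower (camera adjusted p = 2.74e-21), and of the Hox genes, 6 of 21 tested genes were lower (camera adjusted p = 0.0119 and adjusted p = 0.233 with an estimated correlation). Signalling targets were lower too: of the BMP response genes, 7 of 12 tested genes were lower (camera adjusted p = 1.25e-08, with 8 lower when adjusted over the list alone), with Id1 at -6.11 (SE 0.19), and of the WNT response genes, 7 of 13 tested genes were lower (camera adjusted p = 1.17e-08, with 9 lower when adjusted over the list alone), with Sp5 at -5.98 (SE 0.48). Of the trophoblast genes, 2 of 14 tested genes were higher and 7 were lower (camera adjusted p = 0.000408), and Cdkn1a, the p21 cell cycle inhibitor gene, stood at -3.67 (SE 0.51) on a p53 response list where 4 of 10 tested genes were lower (camera adjusted p = 2.4e-06).

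Rhox9 was higher in BP14A than in cytokine-induced cells at day 2 (log2 change 5.37, SE 0.43, adjusted p = 2e-08), as were Dazl at 4.76 (SE 0.56), Dppa3 at 3.29 (SE 0.25), Kit at 2.70 (SE 0.26) and Sox2 at 1.80 (SE 0.20). Of the early germ cell genes, 8 of 13 tested genes were higher (camera adjusted p = 3.01e-07), of the later germ cell genes, 11 of 16 tested genes were higher (camera adjusted p = 5.66e-10), and of the core pluripotency genes, 5 of 11 tested genes were higher and 1 was lower (camera adjusted p = 3.35e-05, with 6 higher and 1 lower when adjusted over the list alone). Dazl stood at 7.77 ± 1.37 in BP14A and 3.01 ± 0.10 in cytokine-induced cells, and already at 7.37 ± 0.14 in EpiLCs. Mael stood at 6.83 ± 0.97, 3.46 ± 0.04 and 9.38 ± 0.12 in these groups. For these 2 later genes the difference thus went with a fall in cytokine-induced cells, not with a rise in BP14A cells. Primed epiblast genes were higher in part, with Fgf5 at 3.47 (SE 0.41) and Otx2 at 2.91 (SE 0.39), while Wnt8a stood at -4.76 (SE 0.27); as a list they were not shifted (camera adjusted p = 0.22, with 3 higher and 5 lower when adjusted over the list alone). In all, 860 genes were higher and 1086 lower in BP14A cells.

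At day 4 the routes differed in 949 genes, against 1946 at day 2. Of the germ cell regulators, Prdm1 (log2 change -0.38, adjusted p = 0.535) and Dppa3 (log2 change 0.25, adjusted p = 0.618) did not pass the test and Prdm14 was lower in BP14A cells (log2 change -1.10, SE 0.25, adjusted p = 0.00775), a call that ended without BP14A day 4 replicate 2 or Ck-PGCLC day 4 replicate 2 (log2 change -1.03 and -1.02) or without the arrays of low Gapdh difference (-1.17). Later germ cell genes were higher, as 11 of 16 tested genes were higher (camera adjusted p = 1.07e-09), with Mael at 2.93 (SE 0.34). Mael stood at 7.67 ± 0.33 in BP14A and 4.74 ± 0.36 in cytokine-induced cells, both under its 9.38 ± 0.12 in EpiLCs. Dnmt3l was higher (log2 change 6.03, SE 0.26, adjusted p = 4.8e-11), at 11.14 ± 0.04 against 5.11 ± 0.12, and Otx2 stood at 3.36 (SE 0.39). Of the streak and mesoderm genes, 9 of 24 tested genes were lower (camera adjusted p = 4.21e-05), led by Hand1 at -5.40 (SE 0.47) and Cdx2 at -5.18 (SE 0.79). In the BMP response list, 1 of 12 tested genes was higher and 6 were lower (camera adjusted p = 4.21e-05), with Id1 at -2.74 (SE 0.19), and of the Hox genes, 4 of 21 tested genes were lower (camera adjusted p = 0.00456 and adjusted p = 0.175 with an estimated correlation). Of the glycolysis and hypoxia genes, 2 of 15 tested genes were higher (camera adjusted p = 0.00128 and adjusted p = 0.0661 with an estimated correlation), of the WNT response genes, 3 of 13 tested genes were lower (camera adjusted p = 0.00246 and adjusted p = 0.0727 with an estimated correlation, with 5 lower when adjusted over the list alone), and of the primed epiblast genes, 5 of 15 tested genes were higher (camera adjusted p = 0.00986 and adjusted p = 0.175 with an estimated correlation, with 6 higher when adjusted over the list alone). The totals were 525 higher and 424 lower, or 598 in all without Ck-PGCLC day 4 replicate 1. The mean Gapdh 5′ minus 3′ difference was -3.82 in BP14A and -1.05 in cytokine-induced cells at day 4, and 547 of the 949 genes remained with that difference as a covariate.

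The difference between the time courses was itself tested, as the change from day 2 to day 4 in BP14A cells minus that in cytokine-induced cells. The streak genes, high at day 2 in the cytokine route, gave 17 of 24 positive differences (camera adjusted p = 1.52e-12), with Lhx1 at 7.28 (SE 0.97) and Hoxb1 at 8.48 (SE 0.65). Early germ cell genes gave 8 of 13 negative differences (camera adjusted p = 1.76e-08), led by Rhox9 at -4.03 (SE 0.60), with Kit at -3.56 (SE 0.36) and Dppa3 at -3.04 (SE 0.36). Of the core pluripotency genes, 6 of 11 tested genes were lower (camera adjusted p = 5.9e-06), of the BMP response genes, 5 of 12 tested genes were higher (camera adjusted p = 0.000199, with 6 higher when adjusted over the list alone), of the WNT response genes, 7 of 13 tested genes were higher (camera adjusted p = 9.61e-05, with 8 higher when adjusted over the list alone), and of the p53 response genes, 3 of 10 tested genes were higher (camera adjusted p = 1.51e-05). The difference was positive for 1073 genes and negative for 763.

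**Figure D2:**
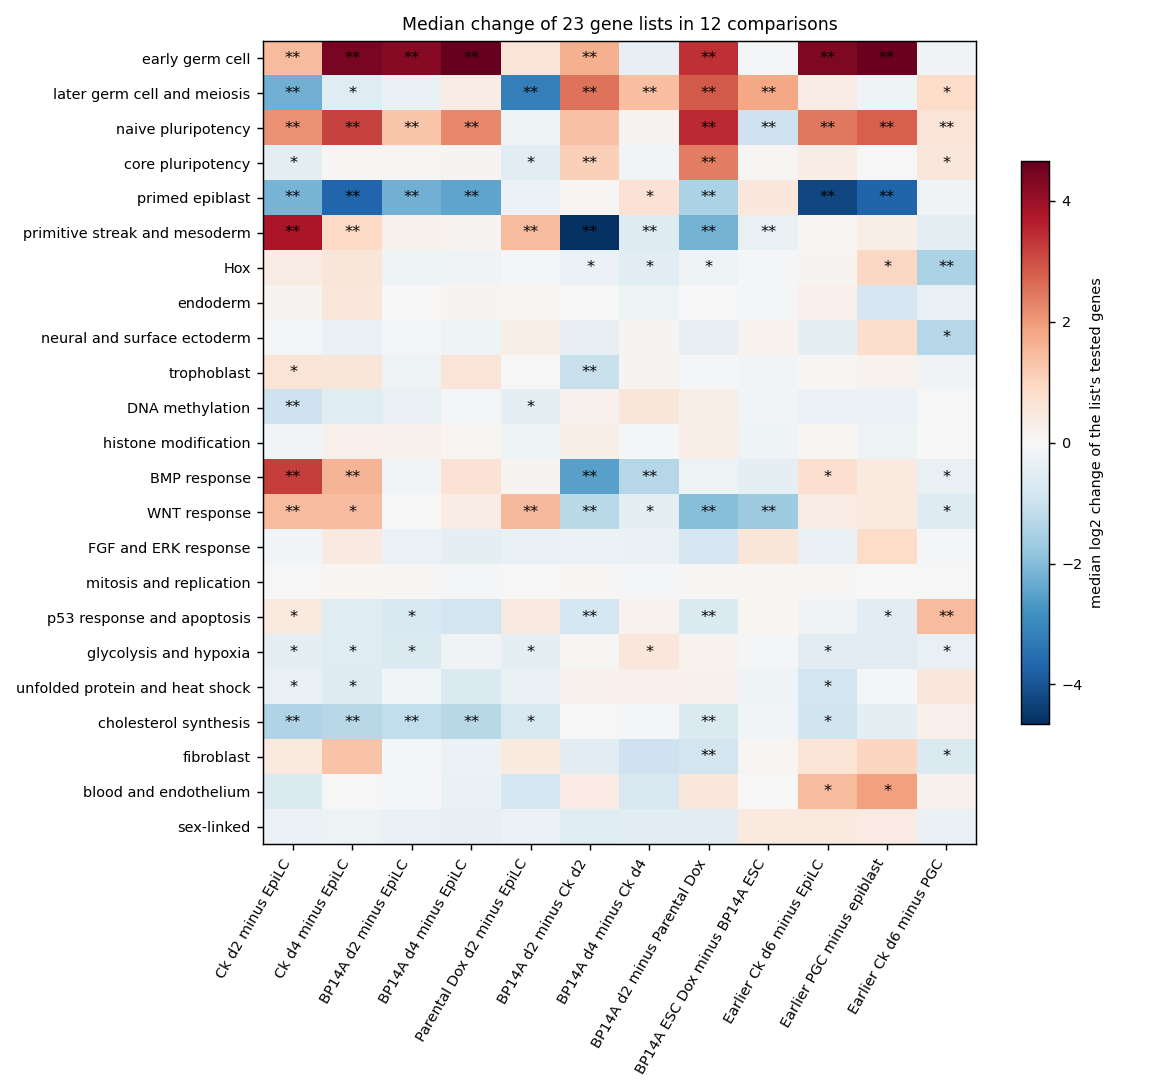
Median log2 change of the tested genes of 23 lists (y axis) in 12 comparisons (x axis), red for higher and blue for lower in the group named first; 1 star marks an adjusted camera p under 0.05 and a pair of stars one that also holds with an estimated correlation. The primitive streak and mesoderm list had a median of 3.80 in cytokine-induced cells against EpiLCs at day 2 and -4.59 in BP14A against cytokine-induced cells.

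To ask how alike the routes were as a whole, BP14A day 2 minus parental +Dox was set against Ck-PGCLC day 2 minus EpiLC, which share no array. Across 15497 genes, which are not independent replicates, Pearson's r was -0.364 and Spearman's rho -0.279, with a covariance of -0.344 (simulated unchanged groups gave 0.001 and 0 on average for r and covariance). The genes higher in both numbered 110, where independent lists of these sizes would share 86.6. Those lower in both numbered 75 against 68, and 739 went opposite ways. With EpiLCs as the control of both routes, r was 0.454 and the covariance 0.359, against simulated means of 0.5 and 0.072 for unchanged groups over the same control, a difference in covariance of 0.287. There 434 genes were higher in both against 81.6 for independent lists, and 345 lower in both against 50.3. At day 4, again over EpiLCs, r was 0.756 and the covariance 0.669, against the same simulated means, a difference in covariance of 0.597, and 803 genes were higher and 598 lower in both, against 113 and 67.6 for independent lists, which leave out the shared control. The 2 control arrays were not split, since neither part would keep 2, so part of the excess of the counts may come from the shared arrays; the simulated covariance of 0.072 is what they add to the covariance. The sign of the day 2 comparison depended on the control used. Hoxb1 rose over EpiLCs in parental +Dox cells (7.6) as in Ck-PGCLCs at day 2 (7.2). Such a change is kept in Ck-PGCLC minus EpiLC but subtracted in BP14A minus parental +Dox. It thus counts as opposite unless BP14A cells made it as well. The simulated unchanged groups hold no such change, so the negative r does not measure how unlike the routes were.

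Parental cells with doxycycline alone, the negative control, had also moved away from EpiLCs by day 2. Hoxb1 rose from 3.62 ± 0.12 to 11.22 ± 0.33 (log2 change 7.60, SE 0.46, adjusted p = 4.78e-10), Lhx1 rose by 7.78 (SE 0.68), Sp5 by 7.21 (SE 0.48) and the posterior neuromesodermal gene Nkx1-2 by 7.80 (SE 0.55). Of the streak and mesoderm genes, 13 of 24 tested genes rose (camera adjusted p = 5.81e-10), and of the WNT response genes, 7 of 13 tested genes rose (camera adjusted p = 7.09e-08, with 8 higher when adjusted over the list alone). The endoderm gene Foxa2 rose by 6.29 (SE 0.34). Later germ cell genes fell, as 12 of 16 tested genes fell (camera adjusted p = 7.11e-14), with Dazl at -6.75 (SE 0.56), and Dppa3 changed by -2.54 (SE 0.25) and Rhox5 by -4.73 (SE 0.34). Tfap2c and Prdm1 rose by 2.09 (SE 0.29) and 1.42 (SE 0.33), the latter call ending without EpiLC replicate 1 (log2 change 0.98), also when the other arrays of low Gapdh difference were left out with it, while Prdm14 did not pass the test (log2 change -0.12, adjusted p = 0.788). The early germ cell list was not shifted (camera adjusted p = 0.821). Nanog rose (log2 change 4.16, SE 0.45, adjusted p = 1.01e-06), but the core pluripotency gene Dppa2 changed by -6.30 (SE 0.27), and of that list 1 of 11 tested genes rose and 5 fell (camera adjusted p = 0.000227 and adjusted p = 0.0759 with an estimated correlation). Of the DNA methylation genes, 1 of 12 tested genes rose and 4 fell (camera adjusted p = 0.00952 and adjusted p = 0.0874 with an estimated correlation), and of the glycolysis and hypoxia genes, 4 of 15 tested genes fell (camera adjusted p = 0.0148 and adjusted p = 0.132 with an estimated correlation). The totals were 1120 higher and 872 lower.

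Against these controls, BP14A cells had higher germ cell genes. All 13 tested early germ cell genes were higher (camera adjusted p = 4.65e-17, and 6.11e-12 without the 3 factor genes), led by Rhox9 (log2 change 9.80, SE 0.43, adjusted p = 7.2e-12), at 10.90 ± 0.19 against 1.10 ± 0.42, with Dppa3 at 7.04 (SE 0.25). Of the later germ cell genes, 11 of 16 tested genes were higher (camera adjusted p = 7.44e-11), with Dazl at 7.14 (SE 0.56); Dazl stood at 7.77 ± 1.37 in BP14A, 7.37 ± 0.14 in EpiLC and 0.62 ± 0.71 in parental +Dox cells, where it had fallen. Of the naive genes, 9 of 14 tested genes were higher and 2 were lower (camera adjusted p = 4.27e-07), with Esrrb at 6.27 (SE 0.53), and of the core pluripotency genes, 6 of 11 tested genes were higher and 2 were lower (camera adjusted p = 2.68e-07). Streak genes were lower, as 14 of 24 tested genes were lower (camera adjusted p = 3.86e-10), and so were WNT response genes, as 8 of 13 tested genes were lower (camera adjusted p = 1.37e-07). Hoxb1 stood at -8.86 (SE 0.46) and Fst at -8.52 (SE 0.41). Primed epiblast genes were lower (8 of 15, camera adjusted p = 3.75e-07), with Dnmt3b at -3.53 (SE 0.61). Of the p53 response genes, 5 of 10 tested genes were lower (camera adjusted p = 0.000285), of the cholesterol synthesis genes, 3 of 10 tested genes were lower (camera adjusted p = 0.00596), and of the fibroblast genes, 5 of 11 tested genes were lower (camera adjusted p = 0.00596). The totals were 1028 higher and 1123 lower.

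Germ cell genes were also higher than in parental +Dox cells with fewer factors. P14 cells, with Prdm14 alone, had 12 of 13 early germ cell genes higher (camera adjusted p = 1.66e-16), with Rhox9 at 7.95 (SE 0.43), Dppa3 at 6.80 (SE 0.25) and Prdm1 at 10.23 ± 0.09 against 5.63 ± 0.20. In BP14 cells, 12 of 13 tested genes were higher (camera adjusted p = 2.99e-16), with Rhox9 at 8.33 (SE 0.43), and in P14A cells, 12 of 13 tested genes were higher (camera adjusted p = 4.69e-17), with Rhox9 at 7.77 (SE 0.43). Without the 3 factor genes 9 of 10 were higher in each of these (camera adjusted p = 6.14e-11 in P14, 5.24e-11 in BP14 and 1.63e-11 in P14A cells). Of the streak genes, 14 of 24 were lower in each of the BP14, P14A and P14 cells (camera adjusted p = 8.05e-11, 7.52e-11 and 1.1e-10). Later germ cell genes were higher in 11 of 16 cases in each (camera adjusted p = 2.42e-11, 4.8e-11 and 4.23e-09, with 12 in P14A cells when adjusted over the list alone). As a list these genes had fallen from EpiLCs to parental +Dox cells, so higher here need not mean a rise over EpiLCs. Otx2 was higher than in parental +Dox cells in all 3, at 1.99 (SE 0.39), 2.15 (SE 0.39) and 2.06 (SE 0.39). It had fallen in the control, from 9.08 ± 0.19 in EpiLCs to 6.04 ± 0.45. Its levels of 8.03 ± 0.10, 8.19 ± 0.07 and 8.10 ± 0.19 in BP14, P14A and P14 cells lay under that of EpiLCs. In P14 cells, Y-linked genes were lower: Eif2s3y stood at 2.20 ± 0.08 against 8.72 ± 0.06 (log2 change -6.52, SE 0.28, adjusted p = 5.85e-12), and of the sex-linked genes, 3 of 4 tested genes were lower (camera adjusted p = 8.25e-05). BP14 cells gave 990 higher and 996 lower genes, P14A cells 876 and 1056, and P14 cells 982 and 1023. One BP14 array had a Gapdh difference of -4.07 and its partner -0.37.

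Cells with different sets of factors were compared at day 2, each set in its own clone. In BP14A cells, which have Tfap2c beside the factors of BP14 cells, Sox1 was lower (log2 change -5.34, SE 0.56, adjusted p = 7.57e-05), at 0.59 ± 0.83 against 5.93 ± 1.25, as were the kinase gene Pim2 at -2.48 (SE 0.24), the early response gene Egr1 at -2.44 (SE 0.29) and the gap junction gene Gja1 at -2.75 (SE 0.38). With the mean of all its probe sets, Sox1 stood at -2.39 (adjusted p = 0.22). Of the primed epiblast genes, 3 of 15 tested genes were lower (camera adjusted p = 2.1e-10, with 7 lower when adjusted over the list alone). The totals were 7 higher and 44 lower. They moved to 199 without BP14 replicate 2, 13 without its replicate 1 and 9 without BP14A day 2 replicate 2. They moved to 33 with the Gapdh covariate and to 10 without the arrays of low Gapdh difference. Limma had 1276 genes at unadjusted p under 0.05. Fitted on the 4 arrays alone, 0 genes were counted, and Sox1, Pim2, Egr1 and Gja1 had adjusted p of 0.472 to 0.765. In that fit 712 genes had an unadjusted p under 0.05 in limma, fewer than the 0.05 share of the 15497 tested genes that no difference would give.

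BP14A cells differed from P14A cells, which lack the Blimp1 transgene, in 2 lower genes and in no higher gene in limma. The 2 were Eif2s3y (log2 change -2.27, SE 0.28, adjusted p = 0.00228) and the thrombin receptor gene F2r (log2 change -1.28, SE 0.20, adjusted p = 0.0277). In limma, 708 genes had an unadjusted p under 0.05, fewer than the 0.05 share of the 15497 tested genes that no difference would give. Leaving out either P14A array gave a count of 0 (673 and 362 genes at unadjusted p under 0.05), and leaving out either BP14A array gave 4, with F2r at -1.31 and -1.25 and no longer among them; F2r did not pass without the arrays of low Gapdh difference either (-1.28, adjusted p = 0.0648). With the mean of all its probe sets, Eif2s3y stood at -0.71 and did not pass. The primed epiblast list was shifted down with no member counted on its own (median log2 change -0.71, camera adjusted p = 2.07e-10, with 5 lower when adjusted over the list alone), and so was the FGF and ERK response list (median -0.35, camera adjusted p = 0.00036). Against P14 cells, BP14A cells had 9 higher and 11 lower genes, and 1, Erdr1, when only these 4 arrays were fitted. Those higher were led by genes of the sex chromosomes, Erdr1 at 6.75 (SE 0.65), Mid1 at 4.83 (SE 0.45) and Eif2s3y, whose level was 7.20 ± 0.74 against 2.20 ± 0.08 in P14 cells. None of the genes named by the rule as lower passed without each of the 4 arrays in turn. On the primed epiblast list, 1 of 15 tested genes was lower (camera adjusted p = 1.12e-09, with 6 lower when adjusted over the list alone). The total was 10 without P14 replicate 2 and 13 without BP14A day 2 replicate 2. For the interaction of Blimp1 with Tfap2c, limma had 576 genes at unadjusted p under 0.05, again fewer than that share. It passed the test in 0 positive genes and in 4 negative ones, Eif2s3y, Erdr1, Mid1 and Podxl (log2 change -2.16, SE 0.35, adjusted p = 0.0316). That count was 2 without BP14A replicate 2, P14A replicate 1 or P14 replicate 1, 9 without BP14 replicate 2 and 10 without P14 replicate 2. Podxl did not pass without the arrays of low Gapdh difference (-1.96), nor without either BP14A array, either P14A array, BP14 replicate 1 or P14 replicate 1, at log2 differences of -2.23 to -1.94.

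**Figure D3:**
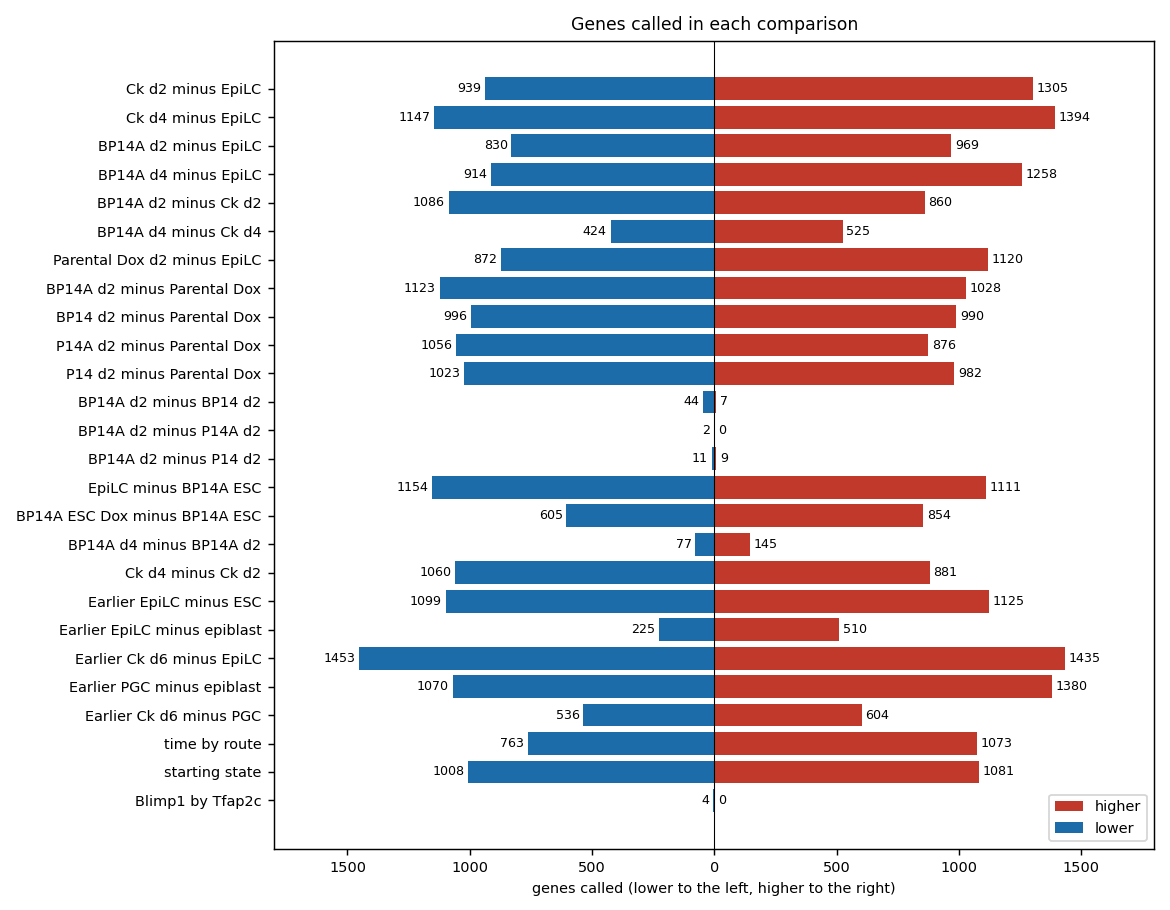
Number of genes counted as higher (red, to the right) or lower (blue, to the left) in the group named first, for the 26 comparisons (y axis). BP14A cells differed from parental +Dox cells in 1028 and 1123 genes, and from P14 cells in 9 and 11.

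In BP14A ESCs, which received doxycycline without an EpiLC stage and were sorted for the stella reporter, naive pluripotency genes fell and later germ cell genes rose. Dppa3, the gene of the reporter, defines that sort and is not a finding. The labels put the untreated ESCs in 2i+LIF and name no medium for the treated ones, so medium is not known to be equal. The WNT target Sp5 fell (log2 change -5.66, SE 0.48, adjusted p = 1.2e-07), with Socs3 at -4.85 (SE 0.45), Klf4 at -4.10 (SE 0.71) and Prdm14 at -2.73 (SE 0.25). Of the naive genes, 7 of 14 tested genes fell (camera adjusted p = 2.74e-06, with 1 higher and 7 lower when adjusted over the list alone), and of the WNT response genes, 8 of 13 tested genes fell (camera adjusted p = 3.09e-07). Of the later germ cell genes, 11 of 16 tested genes rose (camera adjusted p = 4.72e-11), with Piwil2, a piRNA pathway gene, at 3.36 (SE 0.33) and Dazl at 3.35 (SE 0.56). Rhox6 and Rhox9 rose by 4.84 (SE 0.39) and 4.72 (SE 0.43), while the early germ cell list as a whole was not shifted (camera adjusted p = 0.216). Primed markers rose in part, with Fgf5 at 4.38 (SE 0.41) and Dnmt3a at 4.14 (SE 0.27) (camera adjusted p = 0.0616 for the list). Of the streak genes, 4 of 24 tested genes fell (camera adjusted p = 0.0225), led by Gsc (-4.50). The totals were 854 higher and 605 lower, and the Gapdh differences of the sorted arrays were -2.14 and -3.13.

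The difference between BP14A ESCs with and without doxycycline was set against the change from EpiLCs to BP14A day 2 cells, as the former minus the latter. The ESC arm had an untreated control of the same clone and a sort, and the EpiLC arm had the parental EpiLCs and no sort named in the labels, so state, clone, sort and perhaps medium differ together. Early germ cell genes gave 8 negative differences of 13 and 1 positive (camera adjusted p = 1.27e-09, with 1 higher and 9 lower when adjusted over the list alone), led by Prdm14 at -8.22 (SE 0.36) and Tfap2c at -6.55 (SE 0.42), and without the 3 factor genes 5 negative and 1 positive of 10 (camera adjusted p = 0.000281). Prdm14 was already at 10.04 ± 0.07 in ESCs without doxycycline. Primed epiblast genes gave 9 positive and 1 negative differences (camera adjusted p = 1.87e-10, with 10 higher and 1 lower when adjusted over the list alone), with Dnmt3a at 7.74 (SE 0.39) and Pou3f1 at 7.63 (SE 0.55). Of the later germ cell genes, 13 of 16 tested genes were higher (camera adjusted p = 5.21e-10), with Mael at 5.59 (SE 0.48), of the naive genes, 1 of 14 tested genes was higher and 11 were lower (camera adjusted p = 1.87e-10, with 2 higher and 11 lower when adjusted over the list alone), and of the cholesterol synthesis genes, 5 of 10 tested genes were higher (camera adjusted p = 0.000121, with 6 higher when adjusted over the list alone). The difference was positive for 1081 genes and negative for 1008, and the total was 1319 without the arrays of low Gapdh difference.

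The earlier arrays place these cells beside the embryo. EpiLCs differed from the epiblast in 510 higher and 225 lower genes. Stress-linked genes were higher in culture, among them Nupr1 (log2 change 6.97, SE 0.33, adjusted p = 1.27e-10), Atf3 at 5.01 (SE 0.36) and Chac1 at 4.88 (SE 0.20), and of the unfolded protein list, 6 of 12 tested genes were higher (camera adjusted p = 3.5e-07). BMP and lineage genes were lower: Id1 stood at -3.12 (SE 0.19), and of the BMP response genes, 3 of 12 tested genes were lower (camera adjusted p = 7.53e-05). Of the endoderm genes, 6 of 16 tested genes were lower (camera adjusted p = 9.21e-07, with 7 lower when adjusted over the list alone), led by Apoa1 at -4.58 (SE 0.61), and of the streak genes, 7 of 24 tested genes were lower (camera adjusted p = 1.66e-05, with 8 lower when adjusted over the list alone). The histone modification list was shifted down with no member counted (median log2 change -0.34, camera adjusted p = 0.0135). The total was 486 without epiblast replicate 2 and 25 when only these 4 arrays were fitted.

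The early germ cell and primed epiblast lists shifted in the same directions from EpiLCs to day 6 Ck-PGCLCs as from the epiblast to PGCs. All 13 early germ cell genes rose from EpiLCs to day 6 (camera adjusted p = 8.42e-17), with Prdm14 at 7.98 (SE 0.25), and of the primed epiblast genes, 1 of 15 tested genes rose and 12 fell (camera adjusted p = 7.97e-11). Between epiblast and PGCs, of the early germ cell genes, 12 of 13 tested genes rose (camera adjusted p = 5.36e-20), with Rhox9 at 8.57 (SE 0.43), and of the primed epiblast genes, 11 of 15 tested genes fell (camera adjusted p = 2.58e-13), with Otx2 at -8.31 (SE 0.39) and Dnmt3b at -6.55 (SE 0.61). Uhrf1, the partner of the maintenance methyltransferase, changed by -2.90 (SE 0.69) and -2.52 (SE 0.69); the first call ended without EpiLC replicate 1 (-2.12) or day 6 replicate 2 (-2.26), and the second without epiblast replicate 1 (-2.01) or PGC replicate 2 (-1.50). Ehmt1 changed in PGCs (log2 change -1.91, SE 0.24, adjusted p = 4.2e-06). Hox genes rose in PGCs, as 10 of 21 tested genes rose (camera adjusted p = 5.12e-05 and adjusted p = 0.0707 with an estimated correlation). The totals were 1435 higher and 1453 lower at day 6 and 1380 and 1070 in PGCs.

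Set against PGCs, day 6 Ck-PGCLCs had lower Hox and globin genes and higher p53 targets. Of the Hox genes, 9 of 21 tested genes were lower (camera adjusted p = 7.42e-10, with 13 lower when adjusted over the list alone), led by Hoxa2 at -4.12 (SE 0.65). The embryonic globin genes Hbb-y (log2 change -10.01, SE 0.81, adjusted p = 8.6e-08) and Hbb-bh1 at -4.93 (SE 0.60) were lower than in PGCs; red blood cells are the usual source of such transcripts. Emcn (log2 change 2.86, adjusted p = 0.00335) and Cdh5 (2.57, adjusted p = 0.022) of the blood and endothelium list were instead higher in day 6 Ck-PGCLCs. In the other comparison, between epiblast and PGCs, 5 of 9 tested genes of that list rose (camera adjusted p = 0.0197 and adjusted p = 0.11 with an estimated correlation). Of the p53 response genes, 6 of 10 tested genes were higher in day 6 Ck-PGCLCs than in PGCs (camera adjusted p = 2.08e-11), with Phlda3 at 2.74 (SE 0.18). Dazl stood at 3.88 (SE 0.56) on a later germ cell list where 6 of 16 tested genes were higher (camera adjusted p = 9.35e-07 and adjusted p = 0.0522 with an estimated correlation, with 7 higher when adjusted over the list alone). Prdm14 (log2 change 0.22, adjusted p = 0.715) and Tfap2c (log2 change -0.28, adjusted p = 0.675) did not pass the test. Glycolytic genes were lower, as 1 of 15 tested genes was higher and 4 were lower (camera adjusted p = 0.00141 and adjusted p = 0.0564 with an estimated correlation), with Ldha at -3.63 (SE 0.33), and of the neural and surface ectoderm genes, 5 of 13 tested genes were lower (camera adjusted p = 0.00046 and adjusted p = 0.0823 with an estimated correlation, with 7 lower when adjusted over the list alone). The totals were 604 higher and 536 lower, or 171 in all when only these 4 arrays were fitted. In that fit Hoxa2, Hbb-bh1 and Dazl kept their log2 changes but did not pass (limma adjusted p = 0.0927, 0.0634 and 0.096). The PGC arrays differed widely for these genes, with SDs of 1.42, 1.47 and 1.52, against 0.73, 0.39 and 0.11 in day 6 Ck-PGCLCs.

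Over all 26 comparisons and 23 lists, 208 of 598 list tests passed at the preset correlation, and 133 of them also did with an estimated correlation. The early germ cell and primed epiblast lists passed in 20 comparisons each and the later germ cell list in 19. The mitosis and replication list passed in 0, its lowest camera adjusted p being 0.145 with 0 of 26 at unadjusted p under 0.05, and the histone modification list in 1.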

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

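All tests in this part were chosen after their results were seen, except the 3 interactions and the correlation with changes predicted from the Gapdh difference. The change from day 2 to day 4 differed between BP14A and cytokine-induced cells in 1836 genes, and the change from BP14A ESCs without to those with doxycycline differed from that from parental EpiLCs to BP14A day 2 cells, which differ in clone and sort too, in 2089 genes. The effect of Blimp1 differed with and without Tfap2c in 4 genes. Among 4695 tested probe sets without a listed gene, which no comparison uses, 91 were higher and 85 lower in BP14A day 2 than in parental +Dox cells. In groups of 2, a wide spread does not show which of the arrays stands apart.

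The cells labelled P14 had low levels of Y-linked and neighbouring genes, with Eif2s3y at 2.20 ± 0.08 against 8.72 ± 0.06 in parental +Dox cells, Uty at 3.58 ± 0.26 against 6.12 ± 0.30 and Erdr1 at 6.31 ± 0.16 against 12.70 ± 0.13 (SD, n = 2). RNA quality is argued against, since the median change of 5 such genes was -4.29 with the Gapdh difference as a covariate, and a strain variant too, since these genes lay 2.81 higher in C57BL/6 ESCs of the earlier series (median log2; Mid1 alone was low there as well). Loss of the Y chromosome in this line may be the source: of 6 genes on the Y at or over the median level in parental +Dox cells, 3 were lower in P14 cells. Zfy2, Tspy-ps and Uba1y were not. Zfy2 stood at 5.56 and 7.18 in P14 replicates 1 and 2 and at 5.15 and 7.10 in those of parental +Dox cells, thus not lower at either number. Uba1y stood at 5.03 ± 0.25 in P14 but only at 5.17 ± 0.36 in parental +Dox cells. It was higher in BP14A than in P14 cells (log2 change 1.89, SE 0.35, adjusted p = 0.0349). Whether the probe sets of these genes read other genes is not known. A loss of the chromosome thus cannot be told apart from a loss of expression without a loss of the chromosome. Eif2s3y was also low in BP14A ESCs (5.15 ± 0.46) and accounts with Erdr1 and Mid1 for 3 of the 4 genes of the Blimp1 by Tfap2c interaction, which therefore leaves Podxl.

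BP14A and cytokine-induced cells at day 4 differed in 949 genes, while their mean Gapdh difference was -3.82 and -1.05. At least 96.3% of the 949 were counted the same way with deposited or median-centred values, which argues against the choice among these scalings as the cause. The scalings hardly differed here, with a median log2 change of 0.01, 0 and 0.04 for quantile-normalized, deposited and median-centred values. A difference in array levels removed before the values were deposited cannot be seen by this test. With the Gapdh difference as a covariate, 547 of the 949 genes were counted the same way. The covariate fit itself picked these genes, so their staying counted does not argue against 3′ bias as their cause. The covariate was chosen after the data were seen and kept genes of larger change, with a median absolute log2 change of 1.73. For the other 402 the call ended, with the median absolute log2 change going from 1.30 to 0.97 and its SE from 0.33 to 0.38. Across the 949 genes the change correlated at r = 0.237 with the change predicted from Gapdh slopes inside the other groups. That lay between the bounds of 0.2 and 0.5 set for it. By this test RNA quality and induction route cannot be told apart over the 949 genes, the 547 included.

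Primitive streak genes were high in Ck-PGCLCs at day 2 and not in BP14A cells. A mixture of germ cell-like cells with cells like the parental +Dox cells cannot exceed both parts, yet 9 of the 19 streak genes that rose were higher in Ck-PGCLCs than in EpiLCs, parental +Dox and BP14A cells, among them Hand1 and Msx2; for these 9 a difference between clones is argued against as the whole cause too, since Ck-PGCLCs and parental +Dox cells are of 1 clone. Of the other 10 genes, 9 were lower than in parental +Dox cells in each of BP14A, BP14, P14A and P14 cells, which argues against a difference that arose in the BP14A clone alone. A lower share of cells of the BP14A kind is argued against too: the rise of early germ cell genes over EpiLCs, as a share of that in BP14A cells, differed 22.1-fold between the highest and the lowest of the 9 genes counted as higher in both and not dim; and so is RNA quality, as 19 streak genes were lower in BP14A cells with the Gapdh covariate as well. What stays open for the 9 genes is a hypothesis that cytokines may raise them over parental +Dox cells, which also received doxycycline. A mixture with other cells that arise under cytokines was not tested, and the labels name no sort for the PGCLCs. Among the 9, Evx1 stood at 3.76 in BP14A, 8.82 in parental +Dox cells and 11.03 in Ck-PGCLCs, but Hand1 at 3.06, 2.49 and 9.88. For genes such as Evx1, and for the other 10, the factors themselves and anything else that the transgenic lines share stay open too. These were not tested apart. The other 10 were not shown to be higher than without cytokines (Gsc stood at 5.41 against 8.19 in parental +Dox cells).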

How the results depend on the processing

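The alternatives of RNA quality (the Gapdh covariate, and the fit without 5 arrays of low Gapdh difference), the early germ cell list without the 3 factor genes and those of route agreement other than the shared control, Spearman's rho and counted genes only were chosen after the data were seen. Of 454 recounts of genes, 378 came within 1.5 times the reported count and 76 did not. Of 2956 refits of named genes, 2895 kept the direction and the side of the threshold, 58 kept the direction only and 3 reversed, all in ESCs with doxycycline and without a call: Prdm1 (log2 change 0.02 with the Gapdh covariate) and Tfap2c (0.08 without the arrays of low Gapdh difference and 0.10 without replicate 2 of these ESCs, but -0.20, not reversed, without replicate 1); of 553 list tests, the numbers were 515 with the side kept, 27 weaker, 4 stronger and 7 reversed. The reversed list results were likewise without a call: the streak list in BP14A day 2 against EpiLC cells with deposited values (camera adjusted p = 0.91) and median centring (0.815), the early germ cell list in parental +Dox against EpiLC cells (0.953 and 0.965, and 0.535 without the 3 factor genes), the WNT response list in BP14A day 2 against EpiLC cells by its percentile among random lists (58.9) and the early germ cell list in ESCs with against without doxycycline (25.1). This last list passed without the 3 factor genes (camera adjusted p = 0.0101, but 0.115 with an estimated correlation), with Dppa3, which the sort fixes, still on it. Of 134 list results in the text, 24 lost their call with an estimated correlation.

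Without the fold limit, by construction more genes counted: 3920 for Ck-PGCLC day 2, 4444 for Ck-PGCLC day 4, 3066 for BP14A day 2, 3907 for BP14A day 4 and 3678 for parental +Dox against EpiLC cells; 3243 and 1754 for BP14A against Ck-PGCLC at days 2 and 4; 3579, 3440, 3267 and 3355 for BP14A, BP14, P14A and P14 against parental +Dox cells. It gave 3826 for EpiLCs against BP14A ESCs, 2496 for doxycycline in ESCs, 357 and 3305 for day 4 against day 2 in BP14A and cytokine-induced cells, and, in the earlier series, 3776 for EpiLCs against ESCs, 1481 against the epiblast, 4930 for day 6 against EpiLCs, 4263 for PGCs against the epiblast and 1917 for day 6 against PGCs. At an adjusted p under 0.01, fewer counted: 16 for BP14A against BP14, 1 against P14A and 9 against P14 cells, 74 for BP14A day 4 against day 2 and 468 for earlier EpiLCs against the epiblast.

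Fitting only the groups compared leaves fewer arrays to estimate the spread and gave 1123 for BP14A day 2 against EpiLC cells, 0 against BP14 and 0 against P14A cells (712 and 928 at unadjusted p under 0.05 in limma), 1 against P14 cells, 0 for BP14A day 4 against day 2 (1966 unadjusted), 25 for earlier EpiLCs against the epiblast, 1503 for PGCs against the epiblast, 171 for day 6 against PGCs and 2 for the Blimp1 by Tfap2c interaction. The 712 is fewer than the 0.05 share of the 15497 tested genes that no difference would give, and the 928 is not. Fitting only the new or only the earlier arrays gave 94, 6 and 33 for BP14A against BP14, P14A and P14 cells, 305 for earlier EpiLCs against the epiblast, 756 for day 6 against PGCs and 8 for the interaction.

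For BP14A against BP14 cells the count of 51 became 29 with the mean of all probe sets, 33 with the Gapdh covariate and 10 without the arrays of low Gapdh difference. Against P14A cells it became 1 with the mean of all probe sets and 1 without those arrays, and against P14 cells 13 with no filter on dim genes and 9 without those arrays. BP14A day 4 against day 2 gave 134 with the covariate and 78 without those arrays, and the starting state interaction 1319 without them. The Blimp1 by Tfap2c interaction gave 7 with the filter at the 60th percentile, 7 with trend and robust options, 7 with the Gapdh covariate, 1 with the mean of all probe sets and 1 without those arrays. In all of these but the fits on fewer arrays, the cause was not tested. A replicate block moved 1 count by over 1.5 times, BP14A against BP14 cells (82). No label ties arrays of the same number together, and their deviations correlated at -0.22 to 0.48 among the new groups but at 0.24 to 0.52 among the earlier ones, so an effect shared by number is not excluded, least of all there.

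Leaving out each array in turn, where the lone array is assumed to vary like the other groups, gave 598 (without Ck-PGCLC day 4 replicate 1) to 775 for BP14A against Ck-PGCLC day 4. It gave 9 (without BP14A replicate 2) to 199 (without BP14 replicate 2), with 13 without BP14 replicate 1, for BP14A against BP14 cells. Against P14A cells it gave 0 (without either P14A array, with 673 and 362 at unadjusted p under 0.05 in limma) to 4 (without either BP14A array), and against P14 cells 10 (without P14 replicate 2) to 15, with 13 without BP14A replicate 2. For BP14A day 4 against day 2 it gave 60 (without day 4 replicate 1) to 137 (without day 2 replicate 1), with 73 without day 2 replicate 2 and 132 without day 4 replicate 2. For earlier EpiLCs against the epiblast it gave 486 (without epiblast replicate 2) to 818. The interaction gave 2 (without BP14A replicate 2, P14A replicate 1 or P14 replicate 1) to 10 (without P14 replicate 2), with 9 without BP14 replicate 2. The counts of the other 19 comparisons moved by less.

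Route agreement, r = -0.364, was -0.279 as Spearman's rho, -0.402 over counted genes only, -0.364 with deposited values, -0.364 with median centring and -0.362 with the mean of all probe sets. It was -0.29 and -0.377 without replicate 1 and replicate 2 of each group, and 0.454, reversed, with EpiLCs as the control of both routes, where the shared arrays add to r by construction. Signal over background limits genes under log2 4.05, and the pseudocount alternatives did not apply to log2 values.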

Other observations

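All comparisons and genes of this part were chosen after the data were seen. Ck-PGCLCs at day 2 were also set against parental +Dox cells, which had grown for the same time without cytokines, and 360 genes were higher and 218 lower. The labels name no doxycycline for Ck-PGCLCs, so these groups may differ in doxycycline as well as in cytokines. BMP targets were higher, with Id1 at 3.62 (SE 0.19) and the BMP-binding protein gene Bmper at 5.09 (SE 0.59), and of the list 7 of 12 tested genes (median log2 change 2.76, camera adjusted p = 2.02e-15). The WNT response list was not shifted (adjusted p = 0.726). Naive pluripotency genes were higher in 10 of 14 cases (adjusted p = 1.87e-19), led by Esrrb at 3.95 (SE 0.53), and early germ cell genes in 8 of 13 (adjusted p = 4.4e-16), with Prdm14 at 5.75 (SE 0.25), Rhox9 at 4.43 (SE 0.43) and Dppa3 at 3.74 (SE 0.25). Kit (log2 change -0.41, adjusted p = 0.519) did not pass the test. The list calls of this comparison given here all held with an estimated correlation.

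Of the streak and mesoderm genes, 10 of 24 were higher with cytokines than without and 2 lower (camera adjusted p = 2.15e-08). Those higher were led by Hand1 at 7.39 (SE 0.47) and Msx2 at 5.82 (SE 0.42), which mark posterior and extraembryonic mesoderm, and the lower ones were Gsc at -2.78 (SE 0.65) and Eomes at -1.84 (SE 0.34), genes of the anterior streak. The endoderm gene Foxa2 stood at -5.81 (SE 0.34) and the neural gene Sox1 at -5.43 (SE 0.57). Gata3 and Gata2 stood at 5.04 (SE 0.67) and 4.34 (SE 0.37). Primed epiblast genes were lower in 7 of 15 cases (adjusted p = 1.62e-12), led by Fgf5 at -6.11 (SE 0.41).

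The Y-linked gene Zfy2 split the arrays of several new groups by replicate number. It stood at 5.15 and 7.10 in parental +Dox replicates 1 and 2, at 5.12 and 7.20 in EpiLCs, at 5.22 and 7.32 in P14A cells and at 4.99 and 7.01 in Ck-PGCLCs at day 4. In BP14A ESCs it stood at 7.34 and 7.43.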
